A study of Rattus norvegicus with 6 samples.

How the data were processed

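RNA-seq of RUCA-I cells, a rat endometrial adenocarcinoma line from the Lewis strain, was compared between 3 WT and 3 miR-203 KO samples. Per the labels' protocols, total RNA was isolated from untreated cells and made into strand-specific libraries by the dUTP method, and per the series' design text these were sequenced on an Illumina instrument. Neither poly(A) selection nor ribosomal RNA removal is named in the sources used here.

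Per the submitters' processing notes, the tools were TopHat (version 0.9 as listed), Cufflinks 2.2.1 and Cuffdiff 2.2.1.3 with the genome build rn6. The gene annotation and options are not given in the sources used here. The only file used is the authors' gene table, whose layout is that of a Cuffdiff comparison. Per the file headers, the authors gave 1 FPKM value per group, which pools the 3 samples. The log2 fold change of KO over WT, the test statistic (a score with no fixed range), the p-value and the q-value were computed by the authors, per the file headers. FPKM divides by transcript length and library size, so it is unstable for loci near or below the fragment length and keeps no read depth. Cuffdiff shares reads between overlapping or near-identical transcripts, so paralogs such as histone and RT1 genes are uncertain one by one.

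The deposited table holds 26751 rows, of which 26459 were tested by the authors, 272 had too few reads, 19 failed and 1, the mitochondrial row, had too many reads, so no mitochondrial value is used. A gene symbol is missing in 7071 rows. The authors' q-values equalled Benjamini-Hochberg adjusted p-values over the tested rows when recomputed. In 445 of 26694 rows above 0 in both groups, the deposited log2 fold differed from the ratio of the deposited FPKM values by over 0.01. Among them, 5 were called, none of which is a row named in the report. In 25 rows a fold against a KO value of 0 had been overwritten by a spreadsheet and was read as such a fold. The FPKM values sum to 928381 in WT and 1039930 in KO cells.

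The design had foreseen limma on values per sample. Without these no test was run here, and a gene was taken as changed where the authors' q was under 0.05. For gene lists written before the data were examined, the longest locus was taken where a symbol had several rows, and genes needed a mean of at least 1 FPKM over both groups, which left 10714. Each list of at least 5 genes got the median of log2((KO + 1)/(WT + 1)), with a pseudocount of 1, and its percentile among 10000 random lists matched on 10 classes of mean FPKM. The pseudocount understates changes of low genes. Counts adjusted over the list alone apply Benjamini-Hochberg to the authors' p-values of the list. The lists cover literature targets and neighbours of miR-203, epithelial, mesenchymal, keratinocyte, uterine and stromal genes, mitosis, DNA replication, p53, interferon, NF-kB, antigen presentation, TGF-beta, Wnt, Notch, matrix, integrins, cholesterol, hypoxia, stress, miRNA biogenesis, ribosomal proteins and markers of fibroblasts, leukocytes, endothelium, muscle and nerve. The list method was tested on simulated data made by shuffling the 10714 genes. With a planted shift of 0.1, 46% of lists of 10 and 94% of lists of 30 genes fell above the central range. With no shift 5% and 3% fell outside it. Shuffling removes the shared variation of genes of a pathway, so these rates hold for unrelated genes only.

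Named genes follow a rule fixed before the data were examined. It takes the 12 largest increases and 12 largest decreases among called rows with at least 1 FPKM in either group. It also takes up to 4 called members per list by smallest p, and Aspg, Kif26a, Cdh1, Vim, Esr1, Pgr, Tp63, Zeb2, Snai2 and Socs3. For the largest changes, a symbol and values above 0 in both groups were required as well, which the rule as first written did not ask. Some genes that the rule takes are not reported here. Other names were chosen after their values were seen. These include the Hist genes and variants besides the largest increases, members said not to pass other than the fixed genes, calls of a list beyond 4, Rsad2, Csf1r, RT1-A1, the genes of the chromosome 3 run besides Id1, and all genes named in the closing section that the rule does not take.

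The search for shifted runs used rows with a mean of at least 5 FPKM and limited log2 ratios to 1 in either direction. Every run of at least 20 rows per chromosome was scored by its summed deviation over its expected spread. The highest score was compared with 200 shuffled row orders. For simulated data the 855 rows of chromosome 3 were shuffled, including those of the run reported below. A planted shift of 0.2 over a run of 200 rows was recovered with a median overlap of 95.9% and a median statistic of 8.44. A shift of 0.1 gave 82.6% and 4.43, which is under the highest value over shuffled orders (6.21). Shifts of that size can thus be missed in runs of that length, and other lengths were not simulated. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used. A planned test of genes with a miR-203 seed match in the 3' UTR needs transcript sequences and was not run. The gene names of the RefSeq annotation of GRCr8, a different build, were used only to say which genes neighbour each other.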

Results

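RUCA-I is an epithelial cell line derived from a rat endometrial adenocarcinoma, a tumour of the lining of the uterus. Total RNA of untreated, nearly confluent cells was sequenced in 2 groups, 3 batches of wild-type (WT) cells and 3 independently made miR-203 knockout (KO) lines. miR-203 is a microRNA best known from stratified epithelium, where it represses the transcription factor p63. The deposited values are 1 FPKM (fragments per kilobase of transcript, scaled to library size) per gene row and group, so no SD or n stands behind a value here. The only test against the spread between replicates is the authors' own Cuffdiff test, and the read depth of each sample is unknown. All positions are on rn6, with starts and ends as the authors list them.

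The comparison asks which transcripts differ between cells without miR-203 and WT cells. miR-203 itself had no row that could be used, so its loss rests on the labels. Of 12 genes chosen around its locus, 9 were measured and none changed, with a median log2 fold of 0.03 (percentile 71.4 of random lists). Kif26a, beside the locus on chromosome 6 (136720334 to 136753980), stood at 6.98 FPKM in WT and 8.03 in KO cells, with q = 0.997 in the authors' deposited table. Aspg, its other neighbour, had no tested row under its symbol.

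Few genes changed and most changes were small. The authors' deposited table called 277 of 26459 tested rows at q under 0.05, which is 1.05%, with 130 higher and 147 lower in KO cells. Among the 255 called rows above 0 in both groups, 44 were at least 2-fold higher, 47 were at least 2-fold lower and 164 moved by less, in the authors' deposited table. Another 10 called rows were listed at 0 in WT and 12 at 0 in KO cells. The median log2 ratio of KO over WT was 0.01 over rows with a mean of at least 1 FPKM, with quartiles of −0.13 and 0.16. The smallest p in the authors' deposited table was 5e-05, shared by 175 called rows, so p does not rank the strongest changes. WT samples are batches and KO samples separately made lines, so a called difference can belong to the lines as well as to the lost microRNA.

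**Figure D1:**
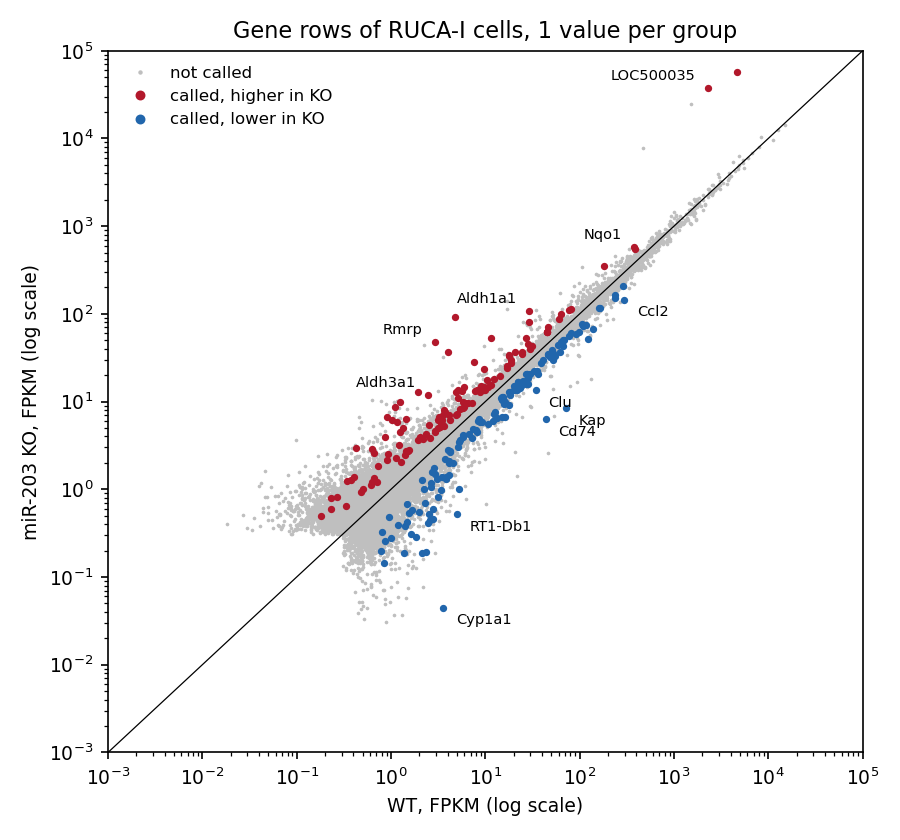
FPKM of each gene row in WT (x axis) and miR-203 KO cells (y axis), both on log scales, for the 26420 tested rows above 0 in both groups. Red and blue points are the 255 of these rows that the authors called higher or lower in KO cells, the line marks equal values, and most called points lie close to the cloud of rows that were not called (grey).

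Among the 12 largest increases were a short non-coding RNA, histone genes and an aldehyde dehydrogenase. The row named Rmrp (chromosome 15, 27738958 to 27739222) rose from 2.94 to 47.7 FPKM, 16.2-fold with q = 0.00756 in the authors' deposited table. Rmrp is the symbol of the RNA component of the mitochondrial RNA processing ribonuclease, and the identity of this row rests on the symbol alone. Aldh3a1, an aldehyde dehydrogenase (chromosome 10, 47490228 to 47499856), rose from 2.49 to 11.8 FPKM, 4.74-fold in the authors' deposited table. The histone genes Hist1h1d (1.24 to 9.99 FPKM), Hist1h2bh (1.10 to 8.67) and Hist1h2ah (1.94 to 12.8) rose, as did LOC684828, LOC684841, LOC690126 and AABR07027753.2, which lie among the histone genes of chromosome 17 (43776028 to 43809079). AC121204.3 (4.82 to 91.0 FPKM) and AABR07000390.1 (4.04 to 36.7) are loci of 226 and 371 bp without a named function, and LOC500035 (2279 to 37327 FPKM) is listed with a locus of 46 bp, for which FPKM is unreliable.

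Of 18 rows with a Hist symbol and a mean of at least 1 FPKM, 5 were called higher in KO cells and none lower, and 13 did not pass, of which 9 were higher. The median log2 ratio of the 18 was 1.86. The 4 that were lower without passing were Hist1h1c (9.10 in WT and 7.65 FPKM in KO cells), Hist1h2bq, and second, shorter rows of Hist1h1d and Hist1h2ai. The 18 rows summed to 83.2 FPKM in WT and 128 in KO cells. H3f3b (266 and 279 FPKM), H2afz (92.2 and 92.9) and H2afy (146 and 140), histone variants made outside S phase, did not pass either. Replication-dependent histone genes are near-identical copies, so the value of a single copy is uncertain.

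**Figure D2:**
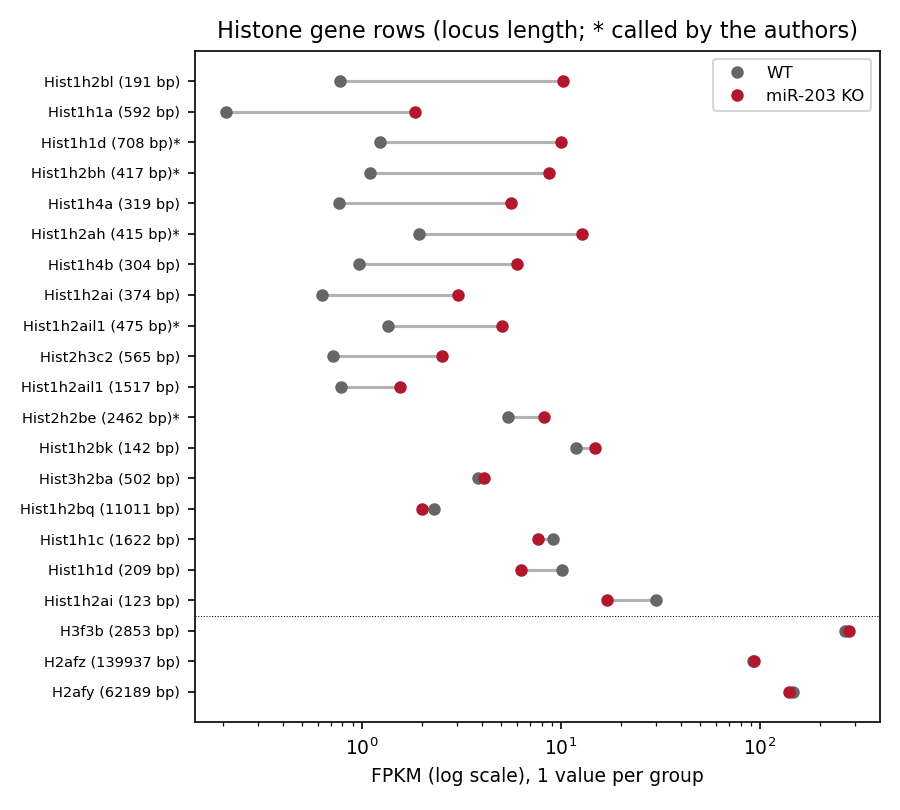
FPKM (log scale) in WT (grey) and miR-203 KO cells (red) for the 18 Hist rows above the dotted line and the 3 replication-independent histone variants below it, with the length of each locus. Points are the authors' single value per group, a star marks a row the authors called, and 14 of the 18 Hist rows lie higher in KO cells.

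Among the 12 largest decreases were genes of MHC class II antigen presentation and Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor. Cd74, the invariant chain of MHC class II (chromosome 18, 56071355 to 56081024), fell from 43.7 to 6.25 FPKM, 6.98-fold with q = 0.00756 in the authors' deposited table. RT1-Db1 (4.98 to 0.522 FPKM) and RT1-Da (1.65 to 0.313), rat class II beta and alpha chains, fell too. The leukocyte markers Cd14 (7.19 in WT and 6.28 FPKM in KO cells) and Cd79a (31.7 and 23.9) did not pass the test, while Csf1r, a leukocyte marker with a mean under 1 FPKM, was called lower (0.791 to 0.2004 FPKM). Cyp1a1 (chromosome 8, 62472120 to 62478118) fell from 3.598 to 0.0447 FPKM, with q = 0.0269 in the authors' deposited table. Its log2 fold of −6.33 in the authors' deposited table rests on a KO value near 0 and is −2.14 with a pseudocount of 1. Kap, kidney androgen-regulated protein, fell from 71.3 to 8.40 FPKM. Decreases were also called for Tac4, Clec2e, AC128059.4, Rn50_X_0743.1, Pgbd5, Fbxo32 and S100a7a, each under 3 FPKM in WT cells at the row named here.

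In the fixed lists, 10 of the 23 with enough members had a median outside the central 95% of random lists matched on expression, 7 below and 3 above, where 1.15 are expected by chance. Medians are of log2((KO + 1)/(WT + 1)) and were small. Genes of a pathway vary together, so these percentiles describe the 2 sets of pooled values and are no test between the groups.

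Genes that respond to p53, the damage-activated transcription factor, were lower as a group. Of 26 members used, 3 fell, none rose and 23 did not pass; adjusted over the list alone, 7 were lower and 1 was higher. Plk2, a polo-like kinase, fell from 55.2 to 33.2 FPKM, Sesn2, a stress-induced regulator of mTORC1, from 12.8 to 7.58, and Ccng1, cyclin G1, from 68.0 to 49.7. The list's median of −0.20 lay below those of all 10000 random lists. Cdkn1a, the p21 inhibitor of the cell cycle, stood at 57.9 and 48.1 FPKM and did not pass.

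The NF-kB and chemokine list had a median of −0.14 (percentile 0.02), where 5 of 23 rows fell, none rose and 18 did not pass (6 lower and 1 higher adjusted over the list alone). Ccl2, which attracts monocytes (chromosome 10, 69411975 to 69413869), fell from 297 to 145 FPKM, 2.05-fold in the authors' deposited table. Its neighbour Ccl7 fell from 4.51 to 1.97 FPKM, Csf2, or GM-CSF, from 2.27 to 0.706, and the row shared by Cxcl2 and Cxcl3 from 107 to 72.2. Csf1 was the remaining call.

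Members of the estrogen and progesterone list for uterus fell in 5 cases and rose in none, and 17 of 22 did not pass (6 lower adjusted over the list alone). Clu, the secreted chaperone clusterin, fell from 34.3 to 13.5 FPKM, Wnt7a from 21.8 to 13.5, C3, complement component 3, from 52.3 to 35.4, and Vegfa, an angiogenic growth factor, from 27.6 to 20.5. Fosl1 also fell. The median was −0.11 (percentile 0.11). Esr1, the estrogen receptor itself, stood at 7.58 and 8.32 FPKM with q = 0.997 in the authors' deposited table. Pgr had no tested row under its symbol.

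Receptors for the matrix and their laminin ligands held further decreases. In the integrin and adhesion list, 3 of 18 members fell and none rose (4 lower adjusted over the list alone), with a median of −0.10 (percentile 0.94). Itga3 fell from 286 to 208 FPKM, Itga6 from 27.6 to 20.6 and Ncam1 from 23.1 to 14.4. Among matrix and protease genes, the laminin-332 chains Lamb3 (61.2 to 36.8 FPKM) and Lama3 (25.1 to 17.02) fell and 16 of 18 did not pass (2 lower adjusted over the list alone), but the median of 0.04 lay inside the random range (percentile 90.7).

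Cholesterol biosynthesis had no called member among 24, yet 18 were lower and the median of −0.14 lay at percentile 0.01; adjusted over the list alone, 1 was lower and 1 higher. DNA replication genes showed a smaller shift of the same kind, with 28 of 35 lower, none called in either way of adjusting and a median of −0.068 (percentile 1.57). The keratinocyte list, 10 genes with none called, had a median of −0.12 (percentile 2.45), which moved inside the range under 6 of 9 other settings. Tp63 had no tested row under its symbol.

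**Figure D3:**
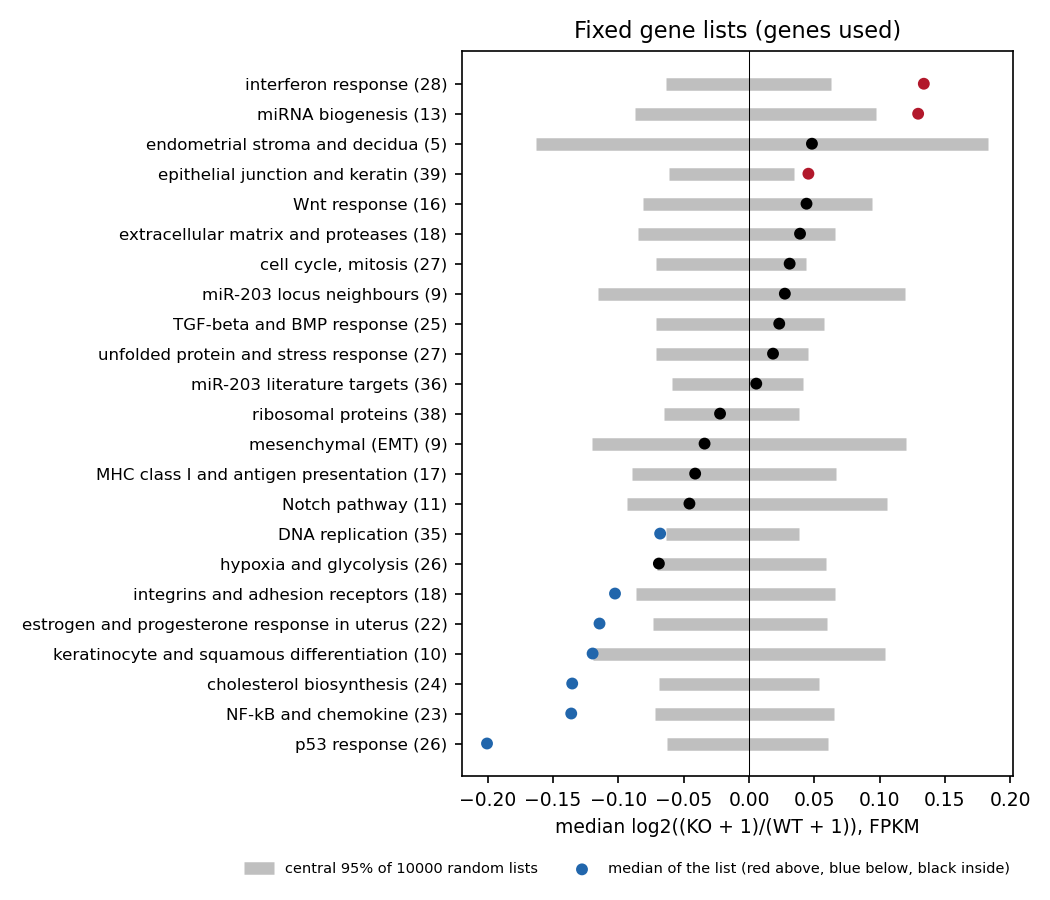
Median log2((KO + 1)/(WT + 1)) of FPKM for each of the 23 fixed lists (points; number of genes used in parentheses) and the central 95% of the medians of 10000 random lists of the same size matched on mean FPKM (grey bars). Blue points, 7 lists, lie below their bar and red points, 3 lists, above it, with p53 response lowest at −0.20 and interferon response highest at 0.13.

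Interferon response genes were higher as a group, where 3 of 28 rose, none fell and 25 did not pass (5 higher adjusted over the list alone). Mx2, an interferon-induced GTPase, rose from 2.35 to 4.32 FPKM, Bst2, or tetherin, from 18.6 to 27.3 and Oasl2 from 6.49 to 9.69. The median of 0.13 lay above all 10000 random lists. Rsad2, which has a mean under 1 FPKM and was left out of that count, was called lower (1.17 to 0.393 FPKM). MHC class I and antigen presentation genes had a median of −0.04 (percentile 20.9), with Cd74 the only call among 17 used (2 lower adjusted over the list alone); RT1-Da, a member with a mean under 1 FPKM, was called lower as given above, and without a filter the median was −0.078 (percentile 3.04). RT1-A1 stood at 188 and 184 FPKM and did not pass. Socs3, a feedback inhibitor of cytokine signalling, stood at 9.88 and 12.4 FPKM with q = 0.565 in the authors' deposited table.

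The miRNA biogenesis list (13 genes, none called in either way of adjusting) had a median of 0.13 (percentile 99.4), which fell inside the random range at percentile 95.1 with a minimum mean of 5 FPKM. Epithelial junction and keratin genes (39 genes, none called in either way of adjusting) had a median of 0.05 (percentile 99.2). Cdh1, E-cadherin, stood at 152 and 144 FPKM and Vim, vimentin, at 440 and 429, and neither passed. The mesenchymal list had a median of −0.03 over 9 genes (percentile 29.1); adjusted over the list alone, 3 were lower and 1 higher. Zeb2 and Snai2 had no tested row under their symbols.

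Genes reported in the literature as miR-203 targets did not stand apart. Of 36 measured, Jun, an AP-1 subunit, rose from 24.6 to 34.6 FPKM, while Hbegf, a ligand of the EGF receptor, fell from 18.2 to 12.9 and Ccng1 fell as given above. The other 33 did not pass, the median was 0.01 (percentile 72.2), and 2 were higher and 2 lower adjusted over the list alone.

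Signalling lists inside the random range held calls in both directions. For TGF-beta and BMP, 2 of 25 rose and 2 fell (4 higher and 3 lower adjusted over the list alone; median 0.02, percentile 84.0). The BMP target Id1 rose from 45.9 to 71.7 FPKM and Bambi, a decoy receptor, from 0.731 to 1.85, while Fst, the activin antagonist follistatin, fell from 3.10 to 1.31. Id1 lies in the part of chromosome 3 described below. In the Wnt list, Fzd5 rose from 3.31 to 5.07 FPKM and Wnt7a fell, and 14 of 16 did not pass (2 higher and 1 lower adjusted over the list alone; median 0.04, percentile 81.0). The unfolded protein and stress list had 1 gene that rose and 4 that fell among 27 (2 higher and 6 lower adjusted over the list alone; median 0.02, percentile 88.0). Nqo1, a quinone reductase, rose from 380 to 578 FPKM, while Asns, asparagine synthetase, fell from 28.4 to 15.9, Chac1, a glutathione-degrading enzyme, from 35.2 to 22.3 and Sesn2 as given above. Hmox1 was also called lower.

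The remaining lists lay inside the range as well. For hypoxia and glycolysis, Vegfa was the only call among 26 (1 lower adjusted over the list alone; median −0.07, percentile 2.85). Mitotic genes had a median of 0.03 over 27 genes (percentile 94.6), Notch genes −0.05 over 11 (percentile 16.3) and ribosomal protein genes −0.02 over 38 (percentile 36.1), with no call in either way of adjusting. Stromal and decidual genes had a median of 0.05 over 5 (percentile 71.7), with none called and 1 lower adjusted over the list alone. Markers of other cell types were too few above 1 FPKM for a percentile. Fibroblast markers gave 3 genes, endothelial 4, muscle 3, leukocyte 2 and neural 0, none of these called; adjusted over the list alone, 1 endothelial, 1 muscle and 1 leukocyte marker were lower.

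By position, the distal part of chromosome 3 stood apart. A search for runs of shifted genes on each chromosome, made after the values were seen, placed a run of 328 rows from 122803312 to 177163090. Its median log2 ratio was 0.16, and 84.5% of its rows were higher in KO cells against 47.1% of all other rows with a mean of at least 5 FPKM. The edge was not sharp, as the median was 0.071 over the 50 rows before the start and 0.171 over the first 50 within. The search statistic was 9.59, where the highest over 200 shuffled row orders was 6.21. The run held 7 called rows, all higher, among them Tgm2, transglutaminase 2 (179 to 352 FPKM), and Cebpb (10.6 to 14.7). A run of 68 rows on chromosome 19 (551671 to 19921177) with a median of −0.14 also passed the shuffled orders, with a statistic of 6.47. Shuffling parts rows that belong to the same gene, so 6.21 may be too low a bar, above all for the run on chromosome 19.

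**Figure D4:**
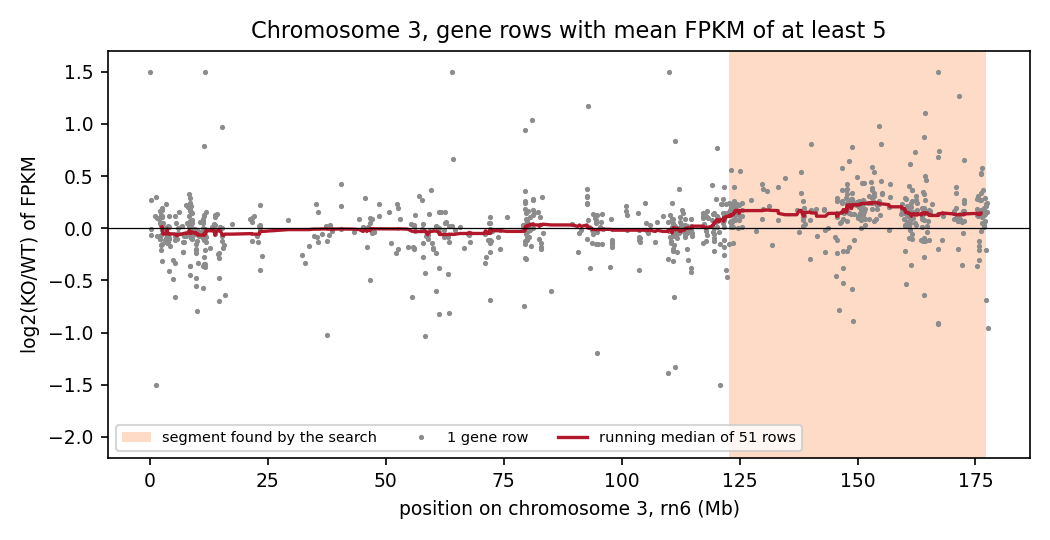
log2(KO/WT) of FPKM (y axis) against position on chromosome 3 of rn6 in Mb (x axis), for 855 gene rows with a mean of at least 5 FPKM; rows beyond 1.5 in either direction are drawn at that value. The red line is the running median of 51 rows, which lies near 0 along most of the chromosome, begins to climb before the start of the shaded run of 328 rows and stays above 0 within it, where the median is 0.16.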

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

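The alternatives named as added, namely the authors' fold column, the row with the highest mean, and leaving out fold mismatches, short loci, unnamed rows, histone rows or the chromosome 3 run, were chosen after seeing the data. The 277 calls became 173 when q was recomputed over rows with a mean of at least 5 FPKM, where fewer rows are tested, 113 when a fold of at least 2 was required as well, and 175 at q under 0.01. Under the other settings the count lay within 1.5 times (239 to 277), including 262 without loci under 300 bp and 270 without the chromosome 3 run. Settings that do not recompute q only remove rows from the 277 calls, so their counts do not test the calls. The number of lists outside the random range was 9 or 10 under all 9 alternatives, and at least 8 of the 10 lay outside on the same side each time. The keratinocyte list kept its place in 3 of the 9 and miRNA biogenesis in 8; the other 8 lists kept theirs in all 9, with medians for p53 response from −0.23 to −0.16 and for interferon response from 0.08 to 0.15. Hypoxia passed below the range without a filter (percentile 2.18) and the stress list above it with a minimum mean of 5 FPKM (percentile 99.8). Folds of named genes kept their direction; 38 values under a pseudocount or quantile normalization moved by over 1.5 times and 136 did not, and apart from LOC500035 those that moved were of genes under 5 FPKM in WT cells. No paired analysis was possible because the table holds 1 value per group. For the same reason the replicate block, leaving out each replicate, limma without trend, array weights, camera, fry, DESeq2, other splits of the samples, the spread within groups and differences between single KO lines were not run, nor pseudocounts for the calls, and the seed match test with its alternatives was not run for want of sequences.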

Other observations

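The gene groups of this paragraph were chosen after the values were seen, so their percentiles are not independent evidence. The tests below were also set after that, except the test on loci of 300 to 800 bp, whose outcome was not known when it was set; the DNA replication and interferon lists that they use were written before the data were examined. In a list of enzymes that handle oxidants and foreign compounds, 7 of 29 used were called higher and 1 lower, and the median log2 fold of 0.16 lay above all 10000 random lists. Cyp1a1, an enzyme of this kind that the list does not hold, fell from 3.598 to 0.0447 FPKM. Aldh1a1, a retinaldehyde dehydrogenase, rose from 29.2 to 107 FPKM, Gstm3 from 17.8 to 33.3, Mgst1 from 63.4 to 100.3 and Ptgr1 from 389 to 551, whereas Hmox1 fell from 59.3 to 44.2. Genes of the amino acid response, which ATF4 drives, were lower in 30 of 31 cases with a median of −0.27, below all random lists, and 7 were called, among them Asns, Atf5 (23.7 to 15.2 FPKM) and Mthfd2 (67.0 to 49.8). The stress list without these members had a median of 0.09 (percentile 99.8). Targets of ERK signalling had a median of −0.17 over 22 genes, also below all random lists, with 6 called lower, including Egr1 (7.30 to 3.84 FPKM), Dusp6 (46.5 to 34.9) and Tgfa (40.9 to 30.2).

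Further single loci stood out by value. Rhox5, a homeobox gene of the X chromosome, rose from 11.5 to 52.6 FPKM and Tex13b, also on X, from 7.52 to 28.2. On chromosome 2, all 13 unnamed rows from 194993534 to 195020972 were lower in KO cells, with log2 folds from −3.67 to −1.87 in the authors' deposited table, and 4 were called. On chromosome 4, Sgce fell from 9.27 to 5.78 FPKM and Ppp1r9a from 3.99 to 2.77, and the 4 unnamed rows that lie between them were lower, of which 1 was called (2.12 to 0.190 FPKM). Of these, 3 lie at 29795615 to 29808791 and the other at 29914417 to 29914593 (30.1 and 22.4 FPKM). Another 3 rows of Ppp1r9a were not called, 1 of them higher in KO cells. In GRCr8 the protein-coding gene between Sgce and Ppp1r9a is the imprinted gene Peg10.

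Of 18 Hist rows, 5 were called higher and 13 were not called, 4 of those being lower. The row named Rmrp was also called higher. Going by its symbol, its RNA lacks a poly(A) tail, like those of replication-dependent histone genes. More cells in S phase would raise replication genes too, but their list had a median log2 fold of −0.068. For the 10 Hist rows of 300 to 800 bp, an error common to short loci would appear in the 480 other named loci of that length. Their median was −0.010, with loci around the histone genes of chromosome 17 left out. An error in some loci only stays open, since AABR07000390.1 (371 bp), among the 480, had a log2 ratio of 3.18, and the 10 Hist rows had a median of 2.68. For Rmrp an error of short loci stays open too. The 191 other named loci of at least 200 and under 300 bp had a median of 0.059, but 1 of them, AC121204.3 (226 bp), had a ratio as high. Whether the RNAs of AABR07000390.1 and AC121204.3 carry a tail is not known here. These loci therefore cannot separate an error of short loci from a change in RNAs without a tail. A candidate explanation that stays open is that KO libraries kept more RNA without a tail. The 3 replication-independent histone genes, whose mRNAs carry one, had a median of 0.011, as this explanation needs. That gives it no support, since rows with a mean of at least 1 FPKM had quartiles of −0.13 and 0.16, so most genes would pass. A change in the processing of RNAs without a tail in the KO lines would look the same and was not tested.

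The higher values along distal chromosome 3 may reflect an extra copy of this part in 1 or more KO lines, as a hypothesis. The run was also placed on every other row. Of the 164 rows in between, at least 85.7% lay above the median of the other chromosomes in each class of expression (low, middle, high). A copy gain needs this. It gives a copy gain no support over other regional causes, since any rise along the run would pass. Several rows can belong to 1 gene, so the 164 are not fully independent of the rows that placed the run. A few strong rows do not account for the higher values, since the median over those of the 164 with p of at least 0.05 was 0.14. Nor does expression level, since 0 of 2000 matched random lists reached the median of the 164. Adding 1 copy to 2 in 1 of 3 lines would give a log2 fold of 0.22 and in all lines 0.585. The observed median of 0.16, with an upper quartile of 0.265, lies far under the latter. The copy number of WT cells is not known here, so a gain in all lines from a higher number of copies stays open. The edge was not sharp either, with a median of 0.071 over the 50 rows before the start. Values per line, which would show whether 1 line carries it, were not analysed here, and a regional effect of the lost microRNA was not tested.

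Cd74 and the MHC class II genes RT1-Db1 and RT1-Da were called lower, while RT1-Bb (1.10 in WT and 0.122 FPKM in KO cells) and Ciita, their master regulator (2.69 and 0.413), did not pass the test (for Ciita q = 0.897 in the authors' deposited table, with a fold that differs from the FPKM ratio). A lower interferon response would be one route, and the interferon list had a median of 0.13, in the other direction. That list mixes genes of several interferons, with 21 members higher and 7 lower. It therefore cannot decide on a lower response to interferon-gamma, which induces MHC class II. Leukocytes in the WT cultures cannot be told apart from a change in the epithelial cells: Cd14 had a log2 fold of −0.20 in the authors' deposited table (7.19 and 6.28 FPKM) and Cd79a stood at 31.7 and 23.9 FPKM, levels at which a small share of other cells would be hidden. Csf1r, a macrophage receptor, was called lower (0.791 to 0.2004 FPKM). Of the 19 leukocyte markers listed, only these 3 had a tested row. Loss of the microRNA and differences between lines stay open.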
